A study of Homo sapiens with 12 samples.

How the data were processed

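Total RNA of 12 cultures was read on a human bead array that sets 47231 probes on each of 12 arrays. The cultures were HaCaT with scrambled siRNA, which the titles call Empty-HaCaT with control siRNA, and Edar-HaCaT, which the labels describe as stably expressing Edar, with scrambled siRNA, RelB siRNA or BRG1 siRNA, each as 3 replicates, with RNA extracted 48 h after transfection. Groups were taken from the sample titles and matched to the columns of values by the names the labels give, with 0 columns left unmatched, and no sample was placed by its values.

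The authors deposited a table of signals, in intensity units, that were not normalized; it was checked that no value is below 0 and that the lowest and highest signals are 66.8 and 33745.2. Beside each signal the authors deposited a detection p-value, which rose as the signal fell within each array with 0 breaks of rank, against at least 252 for any other array's column. A second deposited table holds a score per probe and array; it was found to equal the log2 signal minus the array's mean, divided by the array's SD, to within 0.00506, so that each array has a scale of its own. Per the labels GenomeStudio 2011.1 was used, in a role that is not stated. Slides and dates are not given, and no genome build is named, so no coordinates are given.

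Signals were processed with limma 3.58.1 in R 4.3.3, figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were handled with pandas 2.3.3. Background was corrected by the normexp model with the background taken from the detection p-values and an offset of 16, followed by quantile normalization and log2, which is limma's neqc for tables without negative control probes. The precision of all values is limited by the number of arrays per group, 3, and by signal over background: probes with a detection p-value under 0.05 on at least 3 of 12 arrays were kept, 22249 of 47231. Of all probes 30113 were annotated with 1 gene symbol, 8 with several and 17110 with none; of those kept, 16496 had 1 symbol. The probe with the highest mean stood for its gene, which gave 12299 genes. XIST and Y-linked genes, 12 in all, were left out of all tables.

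A linear model with a mean for each of the 4 groups was fitted to all 12 arrays with limma's lmFit, and moderated statistics were taken from eBayes. The comparisons were Edar-HaCaT minus HaCaT, both with scrambled siRNA; RelB siRNA minus scrambled and BRG1 siRNA minus scrambled, both in Edar-HaCaT; and RelB siRNA minus BRG1 siRNA. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 12299 genes of each comparison, and an adjusted p under 0.05 was called a change. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so none was used for a single gene. A gene counted as above background in a group when its detection p-value was under 0.05 on all 3 arrays. For a gene not above background on all 3 arrays of the lower group, the fold is given as at least that between the higher group's mean and the mean of the lower group with each array set no lower than its background level.

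The design, the alternatives, the rule for named genes and 37 gene lists were fixed before the data were examined. The rule names EDAR, RELB and SMARCA4 in every comparison; the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes whose 3 arrays of one group lie above the 3 of the other, or the top 5 each way between RelB and BRG1 siRNA; for each list up to 2 called members with the highest and up to 2 with the lowest change, or, where none is called, the 2 with the smallest p; for each count of shared genes up to 8 per direction; and any measured EDAR signalling component. XIST, Y-linked genes and probes without a symbol are passed over. Lists with at least 5 tested genes, 34 in all, were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 136 tests of 34 lists in 4 comparisons. Camera with an estimated correlation and limma's fry, which tests the list's own genes in one direction or in either, were run as alternatives. Changes of list members were also counted after adjustment over the list alone. Marker lists for T lineage, B lineage, myeloid and pan-leukocyte cells and a list of aryl hydrocarbon receptor targets were added after the values had been seen.

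Genes called in 2 comparisons were counted by direction, beside the count expected if the calls were independent and 100 simulations of unchanged groups that share arrays. The model was tested on simulated data with 200 of 12299 genes changed: it recovered 86.3%, 77.3%, 79.7% and 83.6% of 2-fold changes in the 4 comparisons, in the order given, and 18.3%, 22.7%, 15.3% and 15.8% of 1.5-fold changes, and 9.03%, 5.00%, 6.16% and 4.55% of the calls were false.

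The alternatives were no background correction, normexp without detection p-values at an offset of 50, median centring or cyclic loess in place of quantile normalization, the deposited scores, no filter or a filter on detection on all 12 arrays, the mean of a gene's probes or every probe, a variance trend with robust moderation, array weights, a fit on the compared groups alone, the replicate number as a block, an adjusted p under 0.01, a fold change of at least 1.5, and leaving out each array in turn. Single genes were not followed through the 2 stricter thresholds, so counts of alternatives that ended a gene's call leave them out. A block for slides was not run, because slides are not given. A normalization of the 2 compared groups alone, and one of RelB and BRG1 siRNA arrays without BRG1 siRNA replicate 1, were added after the data had been seen.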

Results

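Expression was measured in HaCaT cells, a human keratinocyte line that became immortal in culture, and in Edar-HaCaT, a line derived from it that stably expresses Edar, the ectodysplasin receptor of the developing skin appendages. Bead arrays read total RNA from 4 groups of 3 arrays each, taken 48 h after siRNA transfection. The groups were HaCaT with scrambled siRNA, titled Empty-HaCaT, and Edar-HaCaT with scrambled siRNA, with siRNA against RelB (gene RELB, an NF-kB subunit) or with siRNA against BRG1 (gene SMARCA4, an ATPase of the BAF chromatin remodelling complexes). The mean signal of an array lay between 282 and 626 intensity units, and 16925 to 19726 of the 47231 probes had a detection p-value under 0.05. The small number of arrays per group limits the precision of every value. Changes of single genes are log2 fold changes unless a fold is named, and a fold given as at least a value belongs to a gene not above background on all 3 arrays of the lower group. Counts of alternative settings under which a gene's call ended leave out the 2 stricter thresholds for a call. The p-values measure the spread between samples that the labels give as separate repeats.

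The 12 arrays fell into 2 sets. The first principal component held 89.4% of the variance and parted the 6 arrays labelled scrambled siRNA from the 6 arrays labelled RelB or BRG1 siRNA. Across genes, Pearson's r was 0.974 to 0.992 between arrays of the scrambled set, 0.965 to 0.992 within the other set and 0.680 to 0.732 between the sets; genes are not independent replicates. On the arrays of each scrambled group, 3 of the 14 basal keratinocyte markers with a probe were above background on all 3 arrays, whereas all 14 were on each siRNA group's arrays. The 3 on the scrambled arrays were ITGA3, ITGB1 and CD44, none of them a keratin or laminin. KRT5 and KRT14, the keratins of the basal epidermal layer, had means of 4.42 and 4.41 (log2 intensity) on the Edar-HaCaT scrambled arrays and of 13.34 and 12.91 on the RelB siRNA arrays. The opposite held for T lineage markers, a list chosen after the values were seen: 13 of 15 were above background on all 6 scrambled arrays and 0 on all 6 siRNA arrays, with 2 of 15 above background on all 3 RelB siRNA arrays. CD3D and CD247, parts of the T cell receptor complex, had means of 12.86 and 12.98 on the Edar-HaCaT scrambled arrays and of 4.40 and 4.65 on the RelB siRNA arrays. Of 10 pan-leukocyte markers, also chosen afterwards, 10 were above background on all 6 scrambled arrays and 1 on all 6 siRNA arrays. Every comparison of an siRNA group with a scrambled group therefore also compared these 2 sets of arrays.

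**Figure D1:**
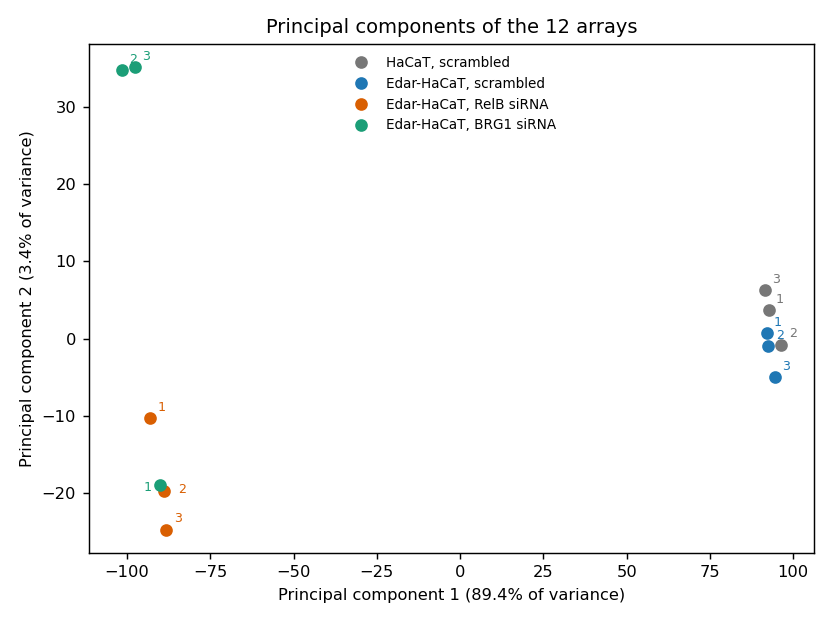
Principal components 1 and 2 of the 12 arrays, from normalized log2 intensities of the 12299 tested genes; each point is an array, coloured by group and numbered by replicate. Component 1, with 89.4% of the variance, parts the 6 scrambled arrays from the other 6, and on component 2 BRG1 siRNA array 1 lies among the RelB siRNA arrays.

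**Figure D2:**
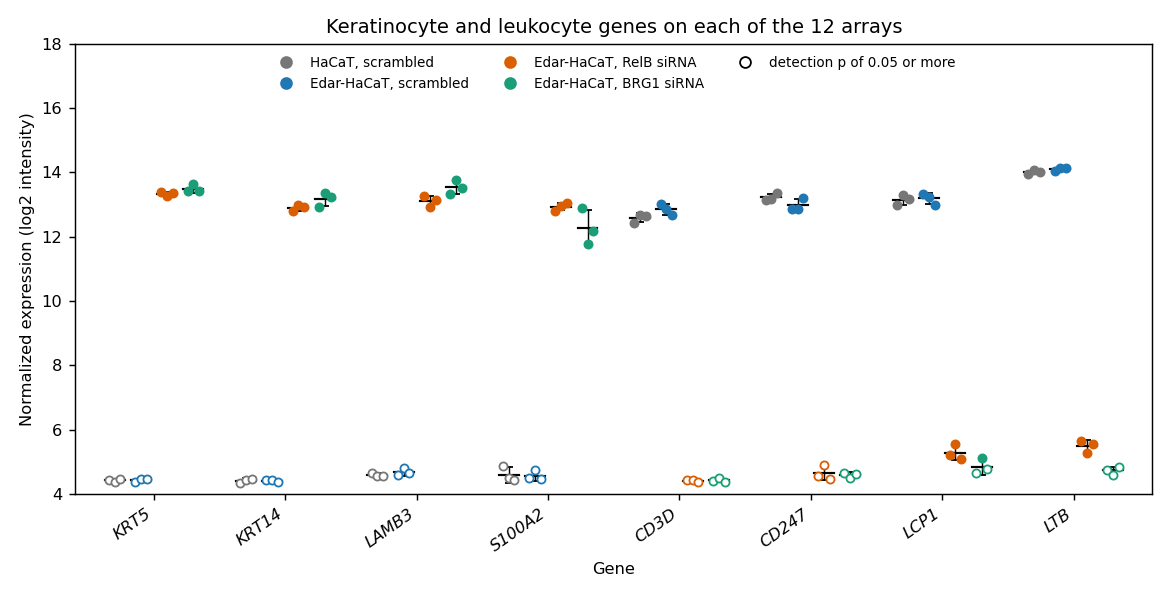
Normalized expression (log2 intensity) of 4 basal keratinocyte or epithelial genes (KRT5, KRT14, LAMB3, S100A2) and 4 leukocyte genes (CD3D, CD247, LCP1, LTB); each point is an array, bars are group means with SD (n = 3), and open points have a detection p-value of 0.05 or more. The keratinocyte genes were at background on all 6 scrambled arrays, and CD3D and CD247 on all 6 RelB and BRG1 siRNA arrays.

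RELB and SMARCA4, the targets of the siRNAs, were lower on the arrays of both siRNA groups than on the scrambled arrays, and EDAR was not detected. RELB had a mean of 7.44 ± 0.19 (SD, n = 3) on the Edar-HaCaT scrambled arrays, 5.76 ± 0.21 under RelB siRNA and 5.76 ± 0.41 under BRG1 siRNA. It was lower than with scrambled siRNA on the RelB siRNA arrays (log2 fold change -1.68, SE 0.20, limma adjusted p = 2.1e-06) and also on the BRG1 siRNA arrays (log2 fold change -1.68, adjusted p = 2.0e-06). SMARCA4 had a mean of 10.93 ± 0.10 with scrambled siRNA, 10.24 ± 0.06 under RelB siRNA and 10.43 ± 0.05 under BRG1 siRNA, a fall in the first (log2 fold change -0.70, adjusted p = 8.2e-04) and in the second (log2 fold change -0.50, adjusted p = 0.0084). Set directly against each other, the siRNA groups did not differ detectably in RELB (log2 difference 0.00, SE 0.20, adjusted p = 1) or in SMARCA4 (-0.19, SE 0.15, adjusted p = 0.53), so a knockdown by either siRNA cannot be shown from these arrays. The scrambled arrays that these falls were measured against had 13 of 15 T lineage markers above background. The EDAR probe was above background on 0 of the 12 arrays, with a lowest detection p-value of 0.069 on an Edar-HaCaT scrambled array, so the stable Edar expression could not be seen with it. A transgene of another species, or one without the probe's sequence, might not be read by this probe, which was not tested.

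**Figure D3:**
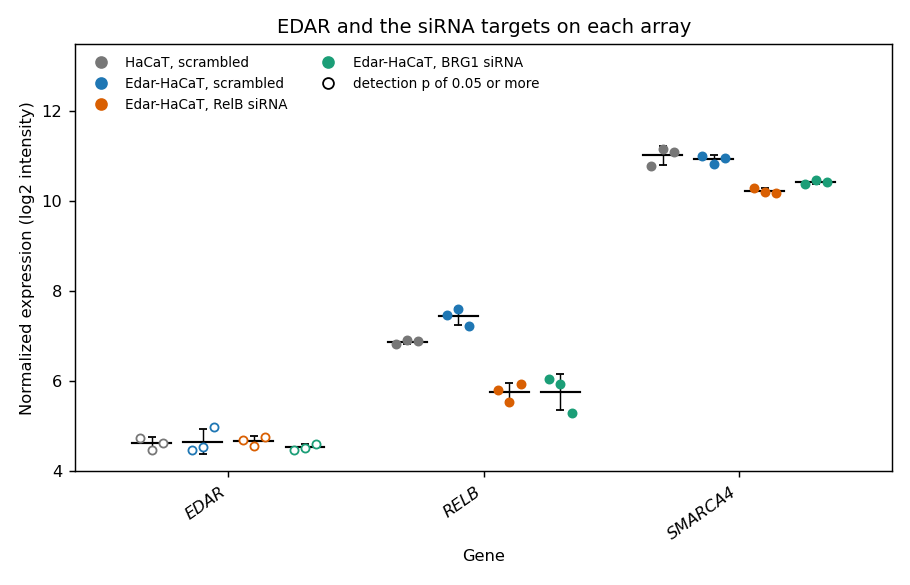
Normalized expression (log2 intensity) of EDAR, RELB and SMARCA4 on each array, by group; bars are group means with SD (n = 3), and open points have a detection p-value of 0.05 or more. EDAR was at background on all 12 arrays, and the RelB and BRG1 siRNA arrays lay at the same mean of 5.76 for RELB.

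Edar-HaCaT and HaCaT, both with scrambled siRNA, were compared to ask what stable Edar expression changes. PANX2, which encodes a channel-forming pannexin, stood highest: its mean was 8.60 ± 0.18 (SD, n = 3) in Edar-HaCaT and at background in HaCaT, so that it was at least 10.8-fold higher (adjusted p = 2.2e-08). SUCNR1, the succinate receptor, rose with a log2 fold change of 3.02 (SE 0.17, adjusted p = 7.7e-08). CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, was at least 4.98-fold higher, and ASB2, a substrate receptor of a ubiquitin ligase, at least 4.73-fold. NQO1, a quinone reductase of the oxidative stress response, rose by a log2 fold change of 2.28, S100P by 2.24, FCGBP by 2.17, PACSIN1 by 2.09, CDKN1A, the cell cycle inhibitor p21, by 1.96 and CALY by 1.74, the largest adjusted p = 0.0043 being that of S100P. In the other direction, THEMIS, a T cell signalling protein, was at least 4.61-fold lower in Edar-HaCaT, where it was at background. IGFBP2, an insulin-like growth factor binding protein, had a log2 fold change of -2.28 (SE 0.18, adjusted p = 4.0e-06). The glycogen branching enzyme gene GBE1 followed with -1.93, the junction gene JAM3 with -1.92, the laminin gene LAMC1 with -1.84, PPP1R1B with -1.77, the cell cycle inhibitor CDKN1C (p57) with -1.76, FAM162A with -1.68 and NSMF with -1.58. The rule that chose these genes required the 3 arrays of one line to lie above the 3 of the other.

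In all, 579 of 12299 genes differed between the lines, 359 higher and 220 lower in Edar-HaCaT, and 178 of them by at least 2-fold. On the arrays of each line, 3 of 14 basal keratinocyte markers and 13 of 15 T lineage markers were above background on all 3 arrays, so the comparison lies within the set of arrays that carried leukocyte transcripts. An effect of Edar in keratinocytes can therefore not be read from it. Replicates of a line also do not tell an effect of Edar from other differences between the lines. The 3 arrays of one line lay apart from the 3 of the other for 26.6% of all genes, against 10% by chance. Among gene lists fixed before the data were examined, 9 of 34 shifted, 4 up and 5 down, by camera with a preset correlation, and 1 of them, the oxidative stress response, also with an estimated one.

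Oxidative stress response genes rose as a group (camera adjusted p = 1.2e-06, and adjusted p = 0.033 with an estimated correlation): 5 of 14 tested members rose, and 8 adjusted over the list alone. They included NQO1 and SRXN1, the sulfiredoxin gene, at 1.18. Of 20 unfolded protein and amino acid stress response genes, 6 rose, with 9 called adjusted over the list alone (camera adjusted p = 3.6e-05, and adjusted p = 0.06 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, rose from a mean of 10.42 ± 0.07 in HaCaT to 11.62 ± 0.02 in Edar-HaCaT (SD, n = 3), and ATF3, a stress-induced transcription factor, was at least 2.22-fold higher, a call that ended without background correction and with the deposited scores. Of 12 TGF-beta and BMP pathway genes, 4 rose, with 4 called adjusted over the list alone (camera adjusted p = 0.0017, and adjusted p = 0.072 with an estimated correlation). ID1, a BMP target, rose by 1.31, and LTBP1, which binds latent TGF-beta, was at least 1.54-fold higher. EGFR ligands and MAPK feedback genes shifted up (camera adjusted p = 0.027, and adjusted p = 0.47 with an estimated correlation), with 3 of 21 higher and 1 lower, 6 adjusted over the list alone. IER3 rose by 1.30 and DUSP5, a MAPK phosphatase, by 0.92, while JUN, an AP-1 subunit, had -0.68, a call that ended under 9 alternatives.

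Hypoxia and glycolysis genes were lower in Edar-HaCaT: 5 of 22 fell, 6 adjusted over the list alone (camera adjusted p = 3.6e-05, and adjusted p = 0.21 with an estimated correlation). PFKFB4, a regulator of glycolysis, had a log2 fold change of -1.87 and P4HA1, a collagen prolyl hydroxylase, of -1.39. Of 11 polyadenylated histone genes, 3 fell, with 5 called adjusted over the list alone (camera adjusted p = 4.1e-05, and adjusted p = 0.2 with an estimated correlation), among them H2BC21, at least 2.18-fold lower, and H2AC6 at -1.01, a call that ended under 5 alternatives. G2/M cell cycle genes shifted down (camera adjusted p = 0.0011, and adjusted p = 0.45 with an estimated correlation), although 2 of 27 fell, also 2 adjusted over the list alone. They were CENPF, a kinetochore protein gene, at -1.40 and MKI67, the proliferation marker Ki-67, at -0.63, whose call ended under 11 alternative settings. Cholesterol synthesis and uptake genes also shifted down (camera adjusted p = 0.0022, and adjusted p = 0.075 with an estimated correlation), with 1 of 20 members lower, also 1 adjusted over the list alone: FDPS, a farnesyl diphosphate synthase, at -0.70, whose call ended under 6 alternatives. Of 8 immune cell markers, 2 fell, PTPRC (CD45) at -1.11 and HLA-DRA at -0.84, with 3 members called adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.14 with an estimated correlation).

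Of 9 tested EDAR signalling components, 0 were called by limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05; MAP3K7 had the largest difference, -0.41 (SE 0.18, adjusted p = 0.22), and EDARADD, the receptor's adaptor, had 0.12. The median of this list was 0.00, its mean -0.05 and the direction of its test down (camera adjusted p = 0.65). Of 17 NF-kB subunits and feedback regulators, 1 fell and 2 were called adjusted over the list alone, and the list did not shift (camera adjusted p = 0.52). The member that fell was CYLD, a deubiquitinase that restrains NF-kB signalling, at -0.66, whose call ended under 4 alternatives. RELB itself had a log2 fold change of 0.56 (SE 0.20, adjusted p = 0.13). Of 13 skin appendage placode genes, MSX1 rose by 0.77 and FGF20 had -0.94; these calls ended under 7 and 6 alternatives, 3 members were called adjusted over the list alone, and the list did not shift (camera adjusted p = 0.47). The chemokine CCL5, the called member of 19 inflammatory cytokines and chemokines, rose by 0.90. The 579 genes became 290 and 307 without HaCaT scrambled array 1 or 3, 337, 366 and 270 without Edar-HaCaT scrambled array 1, 2 or 3, and 883 without BRG1 siRNA array 1, which enters through the shared spread. They became 336 among genes detected on all 12 arrays, 1614 with array weights and 233 at an adjusted p under 0.01.

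**Figure D4:**
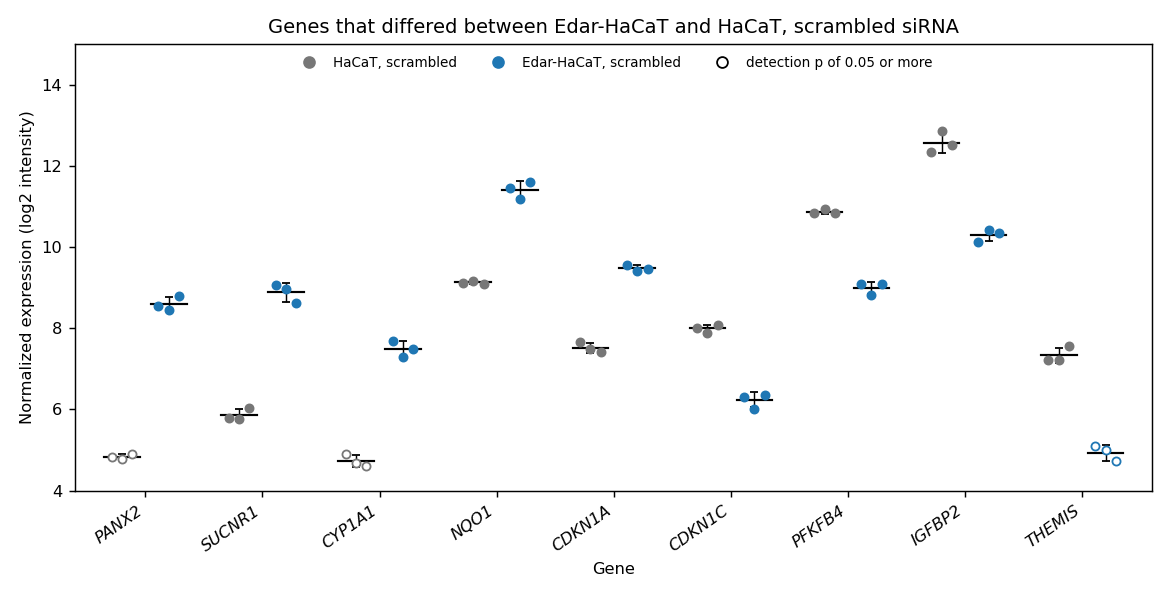
Normalized expression (log2 intensity) of 9 genes that differed between Edar-HaCaT and HaCaT with scrambled siRNA; each point is an array, bars are group means with SD (n = 3), and open points have a detection p-value of 0.05 or more. PANX2 and CYP1A1 were at background in HaCaT and THEMIS in Edar-HaCaT, and for each gene the 3 arrays of one line lay above those of the other.

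RelB siRNA was compared with scrambled siRNA within Edar-HaCaT to ask which genes depend on RelB, and 7485 genes differed, 3542 higher and 3943 lower. That is 60.9% of the 12299 genes tested, the share against which counts of called list members have to be read. The arrays labelled RelB siRNA had 14 of 14 basal keratinocyte markers above background on all 3 arrays and the scrambled arrays 3 of 14. Among the highest genes, TGFBI, an extracellular matrix protein gene, was at least 446-fold higher, and KRT5 and KRT14 at least 298-fold and 221-fold. The laminin-332 chain gene LAMB3 was at least 253-fold higher, the cytokine gene IL1A at least 264-fold, the retinaldehyde dehydrogenase gene ALDH1A3 at least 236-fold, S100A2 at least 226-fold and KRT19 at least 215-fold. These genes were at background on the scrambled arrays and had means from 12.87 to 13.92 (log2 intensity) on the RelB siRNA arrays, the largest adjusted p = 5.1e-14 being that of S100A2. Among the lowest, the smooth muscle actin gene ACTG2 was at least 463-fold lower, CD3D at least 233-fold and CD247 at least 254-fold. LTB, which encodes lymphotoxin beta, had a log2 fold change of -8.62 (SE 0.15, adjusted p = 1.3e-15), its neighbour LTA of -7.56 and the leukocyte actin-bundling gene LCP1 of -7.92, and the interferon-induced IFITM1 was at least 192-fold lower. For 2492 of the 7485 genes the lower group was not above background on all 3 arrays, so that their fitted changes are no measure of size.

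Of the epithelial, epithelial-mesenchymal transition and cytoskeletal gene groups 5 rose on the RelB siRNA arrays, the arrays with 14 of 14 basal markers, and 2 did not shift. All 14 of 14 basal keratinocyte markers rose, also 14 adjusted over the list alone (camera adjusted p = 1.0e-10, and adjusted p = 0.033 with an estimated correlation). Their median log2 fold change was 5.81, or 5.18 with the 11 members not above background on all 3 scrambled arrays taken at their lower bound. Of 20 cell junction genes 17 rose, with 17 called adjusted over the list alone (camera adjusted p = 2.1e-10, and adjusted p = 0.033 with an estimated correlation), among them the desmoglein DSG2, at least 151-fold, and the connexin 26 gene GJB2, at least 132-fold. All 8 of 8 tested stress keratins and alarmins rose, again 8 adjusted over the list alone (camera adjusted p = 3.6e-05, and adjusted p = 0.12 with an estimated correlation). KRT16 was at least 189-fold higher. Of 11 epithelial-mesenchymal transition genes 9 rose, among them TGFBI and SNAI2, a transcription factor also present in basal keratinocytes, and 2 fell, with 11 called adjusted over the list alone (camera adjusted p = 5.9e-04, and adjusted p = 0.06 with an estimated correlation). VIM, which encodes vimentin, fell with a log2 fold change of -2.37. Of 13 keratinocyte and cytoskeletal genes linked to SWI/SNF, 10 rose and 2 fell, with 12 called adjusted over the list alone (camera adjusted p = 6.6e-04, and adjusted p = 0.06 with an estimated correlation). CAV1, the caveolin gene, rose by 7.87 and ACTA2, another smooth muscle actin gene, had -3.33. No shift was found for epidermal differentiation and cornified envelope genes (camera adjusted p = 0.063), of which 7 of 14 rose and 1 fell, with 8 called adjusted over the list alone. Nor was one found for simple epithelial and mucosal keratins (camera adjusted p = 0.27), of which 3 of 5 rose and 2 fell, with 5 called adjusted over the list alone.

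Signalling groups that are active in epithelial cells rose on the same arrays, again with 3 of 14 basal markers above background on the scrambled side. EGFR ligands and MAPK feedback genes rose in 20 of 21 cases and fell in 1, all 21 called adjusted over the list alone (camera adjusted p = 2.9e-09, and adjusted p = 0.072 with an estimated correlation). PHLDA1 rose by 6.61 and FOS, an AP-1 subunit, was at least 72.4-fold higher. YAP and TEAD targets rose in 9 of 11 and fell in 2, with 11 called adjusted over the list alone (camera adjusted p = 1.1e-04, and adjusted p = 0.097 with an estimated correlation), and the tissue factor gene F3 was at least 136-fold higher. Matrix protease and remodelling genes rose in 12 of 16 and fell in 3, with 15 called adjusted over the list alone (camera adjusted p = 8.4e-04, and adjusted p = 0.06 with an estimated correlation). The collagenase MMP1 was at least 15.1-fold higher and the urokinase receptor gene PLAUR had -1.73. Notch pathway genes rose in 10 of 13 and fell in 1, with 11 called adjusted over the list alone (camera adjusted p = 8.4e-04, and adjusted p = 0.06 with an estimated correlation). The ligand gene JAG1 was at least 96.9-fold higher. Wnt pathway genes and targets rose in 9 of 16 and fell in 3, with 12 called adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.25 with an estimated correlation). CCND1 (cyclin D1) was at least 108-fold higher and the transcription factor gene LEF1 had -6.41.

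Stress response and growth arrest genes were also higher on the RelB siRNA arrays than on the scrambled arrays with their leukocyte transcripts. Unfolded protein and amino acid stress response genes rose in 14 of 20 and fell in 1, with 16 called adjusted over the list alone (camera adjusted p = 6.9e-04, and adjusted p = 0.097 with an estimated correlation). DDIT3, the stress factor CHOP, rose by 2.69. Genes of the p53 pathway and cyclin-dependent kinase inhibitors rose in 13 of 20 and fell in 3, with 16 called adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.06 with an estimated correlation). SFN, the epithelial protein 14-3-3 sigma, was at least 121-fold higher and the inhibitor gene CDKN2A at least 44.1-fold. Oxidative stress response genes rose in 8 of 14 and fell in 4, with 12 called adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.13 with an estimated correlation). AKR1C3, an aldo-keto reductase, was at least 34.7-fold higher and NQO1 had -0.72.

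Cell cycle and immune gene groups were lower on the RelB siRNA arrays than on the scrambled arrays, which held 13 of 15 T lineage markers above background. Of 25 DNA replication genes, 23 fell, with 24 called adjusted over the list alone, with a median log2 fold change of -2.46 (camera adjusted p = 2.9e-09, and adjusted p = 0.061 with an estimated correlation). MCM2, a subunit of the replicative helicase, had -4.99 (SE 0.22, adjusted p = 9.5e-12) and MCM10 had -3.45. G2/M cell cycle genes fell in 17 of 27 and rose in 3, with 20 called adjusted over the list alone (camera adjusted p = 0.0054, and adjusted p = 0.51 with an estimated correlation). The kinase gene AURKB had -3.04. Interferon-stimulated genes fell in 24 of 35 and rose in 4, with 28 called adjusted over the list alone (camera adjusted p = 8.4e-04, and adjusted p = 0.06 with an estimated correlation). BST2 (tetherin) had -5.25, whereas IFITM3, which blocks virus entry and is present in many cell types, rose by 5.42. MHC class I antigen presentation genes fell in 11 of 16, with 12 called adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.41 with an estimated correlation). The immunoproteasome gene PSMB9 had -3.45. BAF and PBAF complex subunits fell in 14 of 24 and rose in 2, with 16 called adjusted over the list alone (camera adjusted p = 0.029, and adjusted p = 0.097 with an estimated correlation). PHF10 had -2.42 and BCL11B, a subunit and T cell transcription factor, had -4.06.

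Genes of the pathway named by the siRNA went both ways against the scrambled arrays, which carried leukocyte transcripts. Of 17 NF-kB subunits and feedback regulators, 9 fell and 4 rose, with 13 called adjusted over the list alone, and the list did not shift (camera adjusted p = 0.17). NFKBIE, an NF-kB inhibitor, had -3.38, and TRAF1 was at least 19.6-fold lower, while BIRC2, an inhibitor of noncanonical signalling, rose by 1.74. Their means, 7.09, 4.78 and 10.30 under RelB siRNA, were similar under BRG1 siRNA, at 7.34, 4.96 and 10.23. An effect of RelB on the pathway can therefore not be read from these changes. Of 9 EDAR signalling components, 4 rose, among them the kinase genes CHUK at 1.17 and MAP3K7 at 1.04, and 3 fell, with 7 called adjusted over the list alone (camera adjusted p = 0.65). Inflammatory cytokines and chemokines rose in 8 of 19 and fell in 8, with 16 called adjusted over the list alone (camera adjusted p = 0.77). Their median log2 fold change was 0.08 but their mean -0.48, and the test's direction was down. IL1B was at least 144-fold higher, opposite to LTB and LTA. Skin appendage placode genes rose in 6 of 13 and fell in 5, with 11 called adjusted over the list alone (camera adjusted p = 0.66), with the follistatin gene FST at least 21.6-fold higher. Their median was 0.32 and camera's direction up, but their mean was -0.26 and fry's direction down.

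Across the comparison 18 of 34 lists shifted by camera with a preset correlation, 13 up and 5 down, and 2 of them, the basal keratinocyte markers and the cell junction genes, also with an estimated one. The 3 arrays of one group lay apart from the 3 of the other for 69.7% of genes, against 10% by chance, and 4528 genes changed by at least 2-fold. Because 3 of 14 basal markers were above background on the scrambled arrays and 14 of 14 on the RelB siRNA arrays, a dependence on RelB cannot be separated here from that difference. Among genes detected on all 12 arrays, 4726 differed.

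BRG1 siRNA was compared with the same scrambled arrays to ask which genes depend on BRG1, and 7872 genes differed, 3754 higher and 4118 lower. Counts of called list members have to be read against this share of all 12299 genes, 64.0%. The arrays labelled BRG1 siRNA, like those labelled RelB siRNA, had 14 of 14 basal keratinocyte markers above background on all 3 arrays, against 3 of 14 on the scrambled arrays. The same kinds of gene stood first. TGFBI was at least 569-fold higher, ALDH1A3 at least 390-fold, PRICKLE1, a planar cell polarity gene, at least 377-fold, IL1A at least 351-fold, IL1B at least 344-fold and SERPINB5 (maspin) at least 339-fold. KRT5, KRT14 and LAMB3 were at least 332-fold, 266-fold and 342-fold higher. LTB was at least 537-fold lower, ACTG2 at least 449-fold, the proteoglycan gene SPOCK2 at least 321-fold, CD3D at least 226-fold and CD247 at least 246-fold. LCP1 was at least 281-fold lower (adjusted p = 5.3e-15), S100A4, a calcium-binding protein of motile cells, at least 225-fold, and ITM2A, a T cell membrane protein gene, at least 235-fold. The lower group was not above background on all 3 arrays for 2693 of the 7872 genes.

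Of the epithelial, epithelial-mesenchymal transition and cytoskeletal gene groups 5 were higher on the BRG1 siRNA arrays than on the scrambled arrays, where 3 of 14 basal markers were above background. The other 2 did not shift. All 14 of 14 basal keratinocyte markers rose, also 14 adjusted over the list alone (camera adjusted p = 1.1e-10, and adjusted p = 0.033 with an estimated correlation), with a median log2 fold change of 6.15, or 5.68 with 11 members at their lower bound. Cell junction genes rose in 18 of 20, with 18 called adjusted over the list alone (camera adjusted p = 2.1e-10, and adjusted p = 0.033 with an estimated correlation), among them GJB2, at least 183-fold. All 8 of 8 stress keratins and alarmins rose, again 8 adjusted over the list alone (camera adjusted p = 4.9e-05, and adjusted p = 0.13 with an estimated correlation). KRT16 was at least 229-fold higher. Epithelial-mesenchymal transition genes rose in 9 of 11 and fell in 2, with 11 called adjusted over the list alone (camera adjusted p = 5.9e-04, and adjusted p = 0.06 with an estimated correlation). VIM had -2.28. Keratinocyte and cytoskeletal genes linked to SWI/SNF rose in 10 of 13 and fell in 2, with 12 called adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.06 with an estimated correlation). CAV1 rose by 7.83 and ACTA2 had -3.52. Epidermal differentiation and cornified envelope genes, with 7 of 14 higher and 2 lower, 9 adjusted over the list alone, did not shift (camera adjusted p = 0.12). Simple epithelial and mucosal keratins, 3 of 5 higher and 2 lower, 5 adjusted over the list alone, did not either (camera adjusted p = 0.28). EGFR ligands and MAPK feedback genes rose in 20 of 21 and fell in 1, all 21 called adjusted over the list alone (camera adjusted p = 1.2e-09, and adjusted p = 0.072 with an estimated correlation). PHLDA1 rose by 6.92. YAP and TEAD targets rose in 9 of 11 and fell in 2, with 11 called adjusted over the list alone (camera adjusted p = 1.5e-04, and adjusted p = 0.1 with an estimated correlation), and the ecto-nucleotidase gene NT5E was at least 52.5-fold higher.

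Remodelling, Notch, Wnt and stress groups rose against the same scrambled arrays, with their leukocyte transcripts. Matrix protease and remodelling genes rose in 13 of 16 and fell in 3, with 16 called adjusted over the list alone (camera adjusted p = 4.1e-04, and adjusted p = 0.053 with an estimated correlation). MMP1 was at least 52.6-fold higher. Notch pathway genes rose in 10 of 13 and fell in 1, with 11 called adjusted over the list alone (camera adjusted p = 8.4e-04, and adjusted p = 0.06 with an estimated correlation). JAG1 was at least 102-fold higher. Wnt pathway genes and targets rose in 10 of 16 and fell in 3, with 14 called adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.21 with an estimated correlation). CCND1 was at least 147-fold higher and LEF1 had -6.38. Unfolded protein and amino acid stress response genes rose in 15 of 20 and fell in 1, with 17 called adjusted over the list alone (camera adjusted p = 5.9e-04, and adjusted p = 0.089 with an estimated correlation). DDIT3 rose by 2.30. Genes of the p53 pathway and kinase inhibitors rose in 13 of 20 and fell in 3, with 16 called adjusted over the list alone (camera adjusted p = 0.0077, and adjusted p = 0.067 with an estimated correlation). GADD45A, a growth arrest gene, rose by 5.51 and CDKN1C was at least 2.29-fold lower. Oxidative stress response genes rose in 9 of 14, with 9 called adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.06 with an estimated correlation). AKR1C3 was at least 44.8-fold higher. Hypoxia and glycolysis genes rose in 13 of 22 and fell in 2, with 16 called adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.53 with an estimated correlation). P4HA2, a collagen prolyl hydroxylase, was at least 96.6-fold higher.

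Replication, mitosis and immune groups were lower on the BRG1 siRNA arrays than on the scrambled arrays, which held 13 of 15 T lineage markers. DNA replication genes fell in 21 of 25, with 21 called adjusted over the list alone (camera adjusted p = 1.6e-07, and adjusted p = 0.075 with an estimated correlation). MCM2 had -5.01 (SE 0.22, adjusted p = 8.6e-12) and MCM10 had -3.37. G2/M cell cycle genes fell in 18 of 27 and rose in 2, with 20 called adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.47 with an estimated correlation). PLK1, a mitotic kinase gene, had -2.23. Interferon-stimulated genes fell in 24 of 35 and rose in 4, with 28 called adjusted over the list alone (camera adjusted p = 5.9e-04, and adjusted p = 0.06 with an estimated correlation). BST2 was at least 47.2-fold lower and IFITM3 rose by 4.10. MHC class I antigen presentation genes fell in 10 of 16 and rose in 1, with 11 called adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.42 with an estimated correlation). PSMB9 had -3.89.

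BAF and PBAF complex subunits, the complexes of BRG1 itself, fell in 15 of 24 and rose in 3, with 18 called adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.12 with an estimated correlation). PHF10 had a log2 fold change of -2.42 and SMARCA4 of -0.50, whereas BCL11A, a subunit and transcription factor, was at least 3.54-fold higher. PHF10 and SMARCA4 had means of 6.73 and 10.43 here, and of 6.73 and 10.24 on the RelB siRNA arrays. Their falls were thus not particular to BRG1 siRNA, and were measured against scrambled arrays with leukocyte transcripts. Of 17 NF-kB subunits and feedback regulators, 8 fell and 4 rose, with 12 called adjusted over the list alone, with NFKBIE at -3.13 and TNIP1 higher by 1.15 (camera adjusted p = 0.27). EDAR signalling components rose in 4 of 9, MAP3K7 by 1.49, and fell in 2, with 6 called adjusted over the list alone (camera adjusted p = 0.52). Inflammatory cytokines and chemokines rose in 9 of 19 and fell in 8, with 17 called adjusted over the list alone, with a median of 0.46, a mean of -0.30 and a test direction of up (camera adjusted p = 0.96). Skin appendage placode genes rose in 6 of 13, among them BMP2, at least 7.28-fold, and fell in 5, with 11 called adjusted over the list alone, with a median of 0.28, a mean of -0.44 and a test direction of up (camera adjusted p = 0.78). For these last 2 lists fry's direction was down.

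In all, 19 of 34 lists shifted by camera with a preset correlation, 14 up and 5 down, and 2, again the basal keratinocyte markers and the cell junction genes, also with an estimated one. For 65.6% of genes the 3 arrays of one group lay apart from the 3 of the other, against 10% by chance, and 4852 genes changed by at least 2-fold. A dependence on BRG1 cannot be separated here from the difference in basal and T lineage markers between the arrays. Among genes detected on all 12 arrays, 5052 differed.

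RelB siRNA and BRG1 siRNA were compared directly, both in Edar-HaCaT and both with 14 of 14 basal keratinocyte markers above background, to ask where the 2 siRNA groups differ. CYP1B1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, differed most, with a mean of 6.16 ± 0.22 (SD, n = 3) under RelB siRNA and of 9.17 ± 0.20 under BRG1 siRNA, a log2 difference of -3.001 (SE 0.17, adjusted p = 2.1e-07). CYP1A1, controlled by the same receptor, was at least 4.59-fold lower under RelB siRNA (adjusted p = 4.4e-06). GPAT3, a glycerol phosphate acyltransferase, had -2.42 (adjusted p = 4.4e-06), HSD17B2, which inactivates estradiol and testosterone, -2.15 (adjusted p = 1.6e-05) and the collagenase MMP1 -1.80 (adjusted p = 0.0075). Higher under RelB siRNA were the histone gene H2BC5, at least 4.67-fold (adjusted p = 0.044), and the noncoding RNA gene MIR503HG at 2.07 (adjusted p = 0.0033). TXNIP, a thioredoxin inhibitor, was higher by 1.85 (SE 0.18, adjusted p = 7.7e-05), CCN2, a YAP target that encodes connective tissue growth factor, by 1.80 (adjusted p = 0.0019) and C1orf53 at least 3.21-fold (adjusted p = 0.036). C1orf53 had a mean of 7.44 (log2 intensity) under RelB siRNA, and 7.10, 5.02 and 5.12 on BRG1 siRNA arrays 1, 2 and 3. Its fold, like that of H2BC5, rests on arrays 2 and 3 and does not hold for array 1. CYP1B1, CYP1A1, TXNIP, GPAT3 and HSD17B2 were called under each alternative counted in which they were tested; TXNIP alone of them was tested among genes detected on all 12 arrays. The calls of H2BC5 and C1orf53 ended under 17 and 14 of them, that of MMP1 under 4, and those of MIR503HG and CCN2 under 2, both of which used the 6 arrays alone.

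In all, 267 genes differed, 166 higher and 101 lower under RelB siRNA, and 104 of them by at least 2-fold. The 3 arrays of one group lay apart from the 3 of the other for 18.4% of genes, against 10% by chance. BRG1 siRNA array 1 lay closer to the RelB siRNA arrays (r across genes 0.982 to 0.988) than to BRG1 siRNA arrays 2 and 3 (0.969 and 0.966), which had r = 0.987 with each other. Without BRG1 siRNA array 1 the count was 2174, and without array 2 or 3 it was 34 or 72. Without RelB siRNA array 1, 2 or 3 it was 76, 29 or 60, and without an array of the other groups, which enter through the shared spread, it was 129 and 152 (HaCaT scrambled arrays 1 and 3) and 109, 103 and 128 (Edar-HaCaT scrambled arrays 1, 2 and 3). Fitted on the 6 arrays alone, 11 genes differed.

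Polyadenylated histone genes were higher under RelB siRNA than under BRG1 siRNA: 4 of 11 rose, and all 11 adjusted over the list alone (camera adjusted p = 5.5e-10, and adjusted p = 0.072 with an estimated correlation), among them H2AC6 at 1.56, a call that ended under 2 alternatives. Their median difference, RelB siRNA mean minus 1 BRG1 siRNA array, was 0.44 for array 1 against 1.27 and 1.09 for arrays 2 and 3, and H2BC5 had 8.33 on array 1, 6.47 on array 2 and 4.91 on array 3 (log2 intensity). Oxidative phosphorylation genes shifted up (camera adjusted p = 0.018, and adjusted p = 0.35 with an estimated correlation), with 2 of 22 higher and 12 called adjusted over the list alone, 10 higher and 2 lower. The shift rested on BRG1 siRNA arrays 2 and 3, for which this median difference was 0.47 and 0.46, against -0.02 for array 1. COX6C, a cytochrome c oxidase subunit, was higher by 1.35, with an SD of 0.81 under BRG1 siRNA, a call that ended under 9 alternatives. Matrix protease and remodelling genes were lower, 5 of 16, or 7 adjusted over the list alone (camera adjusted p = 4.8e-04, and adjusted p = 0.053 with an estimated correlation). Oxidative stress response genes were lower in 3 of 14 cases, with 6 called adjusted over the list alone, 5 of them lower (camera adjusted p = 0.0024, and adjusted p = 0.067 with an estimated correlation). NQO1 had -1.05 and the thioredoxin reductase gene TXNRD1 had -1.03, calls that ended under 2 and 4 alternatives. EGFR ligands and MAPK feedback genes shifted down (camera adjusted p = 1.8e-04, and adjusted p = 0.21 with an estimated correlation), with 1 of 21 lower and 10 called adjusted over the list alone, 9 of them lower. The lower gene was EREG, an EGFR ligand, at -1.03, a call that ended under 13 alternatives.

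Hypoxia and glycolysis genes shifted down under RelB siRNA against BRG1 siRNA (camera adjusted p = 0.0029, and adjusted p = 0.4 with an estimated correlation), with 1 of 22 lower, the angiogenic growth factor VEGFA at -1.10 (ended under 4 alternatives), and 8 called adjusted over the list alone, 6 of them lower. DNA replication genes shifted down (camera adjusted p = 6.2e-04, and adjusted p = 0.21 with an estimated correlation), with 1 of 25 lower, or 7 adjusted over the list alone. The lower gene was RRM2, a ribonucleotide reductase subunit, at -0.94, and its call ended under 17 alternatives. Cell junction genes shifted down (camera adjusted p = 0.0055, and adjusted p = 0.17 with an estimated correlation), with 1 of 20 lower and 3 called adjusted over the list alone, 2 of them lower. The lower gene was PKP3, a plakophilin of desmosomes, at -0.70, and its call ended under 13 alternatives. Lipid synthesis genes shifted down (camera adjusted p = 0.014, and adjusted p = 0.16 with an estimated correlation), FASN, the fatty acid synthase, at -0.66 and FADS1, a desaturase, at -0.66, 2 of 16 in all or 4 adjusted over the list alone, with calls that ended under 15 and 17 alternatives. Housekeeping genes shifted down as well (camera adjusted p = 0.0028, and adjusted p = 0.32 with an estimated correlation), with 1 of 12 called, also 1 adjusted over the list alone: TFRC, the transferrin receptor, at -1.14, which ended under 5 alternatives. On BRG1 siRNA array 1 the median difference was -0.07 for hypoxia, -0.09 for DNA replication and -0.07 for housekeeping genes, against -0.48 to -0.41, -0.47 to -0.33 and -0.65 to -0.49 on arrays 2 and 3, so these shifts also rested on the latter. With a preset correlation 10 of 34 lists shifted, 2 up and 8 down, and with an estimated one 0 did, where 5 of 34 had an unadjusted p under 0.05.

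Between the siRNA groups, limma called 0 of 9 EDAR signalling components, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.42). It called 0 of 17 NF-kB subunits and feedback regulators, again also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.29). DKK1, a secreted Wnt inhibitor of the placode list, was higher under RelB siRNA by 1.54 and the small heat shock protein CRYAB at least 2.15-fold. IL1RN, the interleukin-1 receptor antagonist, had -1.34, the chemokine CXCL8 -1.27 and TGM1, a transglutaminase of the cornified envelope, -1.41. Of these calls, that of CXCL8 ended under 6 alternatives, that of DKK1 under 3 and each of the others under 2.

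**Figure D5:**
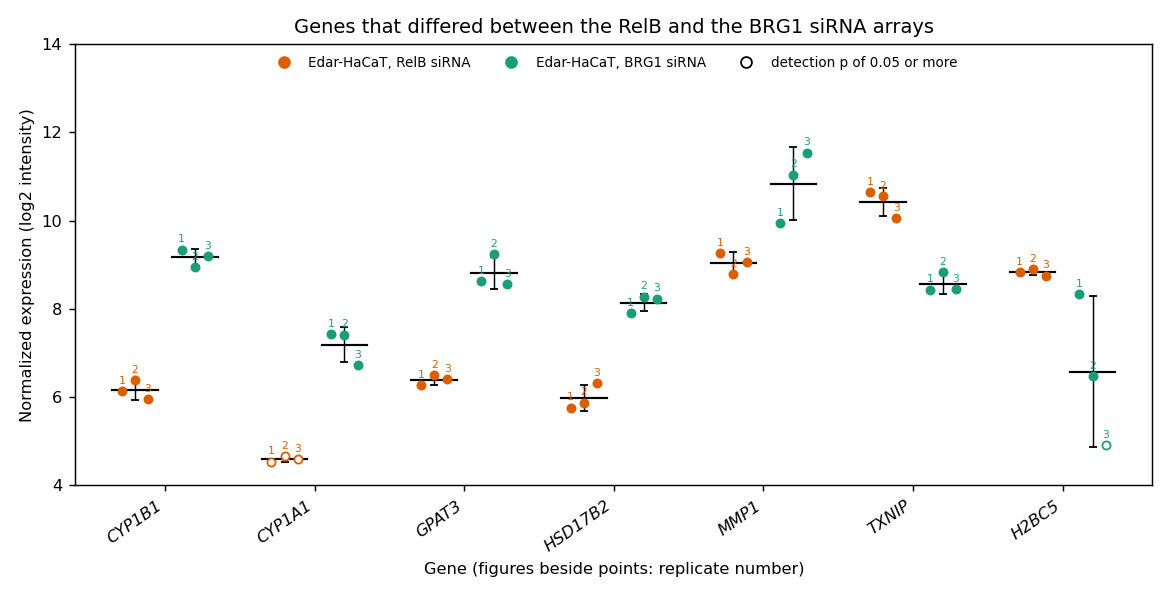
Normalized expression (log2 intensity) of 7 genes that differed between RelB siRNA and BRG1 siRNA in Edar-HaCaT; each point is an array with its replicate number, bars are group means with SD (n = 3), and open points have a detection p-value of 0.05 or more. CYP1B1 and CYP1A1 were lower on each of the 3 RelB siRNA arrays than on each BRG1 siRNA array, and H2BC5 was far apart between BRG1 siRNA array 1 and arrays 2 and 3.

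Genes that differed between Edar-HaCaT and HaCaT and changed the opposite way under an siRNA were counted to ask which Edar-dependent genes need RelB or BRG1. RelB siRNA went with the opposite change in 270 of the 579 genes and with a change in the same direction in 197. Of the 270, 207 were higher in Edar-HaCaT, where 115 would be met if the calls were independent, and 63 were lower, where 63.4 would be met. They included SUCNR1, which was at least 14.8-fold lower under RelB siRNA, the neuronal adaptor gene PACSIN1, at least 21.6-fold, the chemokine receptor gene CCR4, at least 21.5-fold, and CYP1A1, at least 5.63-fold. Among those lower in Edar-HaCaT, LAMC1 rose by 4.89 and GBE1 by 1.40. Under BRG1 siRNA the opposite change was seen in 264 genes and the same direction in 207. Of the 264, 199 were higher in Edar-HaCaT, where 120 would be met if the calls were independent, and 65 were lower, where 67.2 would be met. SUCNR1, PACSIN1, CCR4, LAMC1 and GBE1 were among these too. The basal and T lineage difference between scrambled and siRNA arrays enters each of these counts, and the comparisons share the Edar-HaCaT scrambled arrays. The calls are therefore not independent, and a need for RelB or BRG1 cannot be read from an excess over the independent counts.

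On the RelB siRNA and the BRG1 siRNA arrays 6737 genes differed in the same direction from the scrambled arrays, 3241 up and 3496 down, where 1081 and 1320 would be met if the calls were independent. KRT5, LAMB3, CD3D and MCM2 were among them. The comparisons share the Edar-HaCaT scrambled arrays, so their log2 fold changes are correlated without any effect: across genes, in 100 simulations r was -0.501 for the Edar and RelB siRNA comparisons, -0.5 for the Edar and BRG1 siRNA comparisons and 0.5 for the siRNA comparisons. The data gave -0.0994, -0.0854 and 0.976, but r also depends on the size of real changes, of which the simulations had none. The covariances of the same log2 fold changes were -0.0587, -0.0520 and 2.82, against -0.0226, -0.0226 and 0.0227 in the simulations. The simulations gave a mean of 0.01, 0 and 0 genes in common. With no gene changed in them, that count was near 0 in advance and tests nothing. The count of 270 became 141 and 149 without HaCaT scrambled array 1 or 3 and 163 and 127 without Edar-HaCaT scrambled array 1 or 3, and 178 without array 2. That of 264 became 138 and 143 without HaCaT scrambled array 1 or 3, 160 and 123 without Edar-HaCaT scrambled array 1 or 3, and 403 without BRG1 siRNA array 1. Among genes detected on all 12 arrays the counts were 144, 137 and 4159.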

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

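The tests of whether BRG1 siRNA array 1 holds RNA of the RelB siRNA group, a mixture or a weaker knockdown, and the tests of normalization and of arrays 2 and 3 for CYP1A1 and CYP1B1, were chosen only after the results were seen. No outlier test was run on groups of 3 arrays.

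The direct test of RelB siRNA against BRG1 siRNA arrays called 267 genes and, by camera with a preset correlation, 10 of 34 gene lists. With an estimated correlation camera called 0 lists (5 at an unadjusted p under 0.05), and a fit of the 6 arrays alone called 11 genes. RELB and SMARCA4 did not differ detectably between these groups, so a difference between knockdowns is not shown. Higher under RelB siRNA were H2BC5 (fitted 2.26, log2, at least 4.67-fold), MIR503HG (2.07), TXNIP (1.85), CCN2 (1.80) and C1orf53 (fitted 1.69, at least 3.21-fold). The folds of H2BC5 and C1orf53 rest on BRG1 siRNA arrays 2 and 3, as array 1 lay near the RelB siRNA mean for both genes. Lower were MMP1 (-1.80), HSD17B2 (-2.15), GPAT3 (-2.42), CYP1A1 (fitted -2.59, at least 4.59-fold, as it was at background under RelB siRNA) and CYP1B1 (-3.001). With 10 splits of the 6 arrays a share under 0.05 cannot be reached; the real split gave 267 genes and the highest other 730, so that 2 splits gave as many. The split with 730 genes set RelB siRNA array 1 with BRG1 siRNA arrays 2 and 3 against the rest, which points to a structure of the samples other than the groups. For the lists, adjusted within the comparison, the real split gave 10, the highest other also 10, and 2 splits gave as many.

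BRG1 siRNA array 1 lay nearer to the RelB siRNA arrays than to BRG1 siRNA arrays 2 and 3: over the 2174 genes called without array 1, its median place was 0.101 of the way from the RelB siRNA mean to that of arrays 2 and 3, against -0.114 to 0.127 for RelB siRNA arrays, and 17.5% of genes lay past the middle. Argued against as the whole cause is a label that hides RNA of the RelB siRNA group: among the 278, 238 and 219 genes that part BRG1 siRNA arrays 2 and 3 from 2 RelB siRNA arrays by more than 1.5 (log2), array 1 lay with arrays 2 and 3 on 10, 12 and 12, where a RelB siRNA array did so on at most 2, although its median places there, -0.0131 to 0.0432, were within those of the RelB siRNA arrays, -0.0865 to 0.143. Arrays 2 and 3 had the lowest mean signals of the 12 arrays, 311 and 282 intensity units. Among the 3075 brightest genes array 1 differed from them 2.52 times as much as the most distant RelB siRNA array from its group. Among the 3075 dimmest genes this ratio was 1.10. Lower signal that adds spread to dim genes alone is thus argued against as the whole cause. Lower signal that also changes bright genes stays open, because the test takes bright genes to be unaffected. A mixture of RNA of both groups would need 1 share for all genes. At least 9 genes needed a share of RelB siRNA RNA under 0.25 while most needed over 0.75, with medians of 0.93 to 1.03. A RelB siRNA array, measured against the other 2, had at most 1 gene under 0.25. On BRG1 siRNA array 2, 13 genes lay as far out, but it was measured against array 3 alone. The test does not decide between these yardsticks. Of genes named above, array 1 lay at 1.09 for CYP1B1, 1.14 for CYP1A1, 1.11 for TXNIP, 0.89 for GPAT3 and 0.85 for HSD17B2. Here 0 is the RelB siRNA mean and 1 that of arrays 2 and 3. H2BC5 at 0.16, C1orf53 at 0.14 and MMP1 at 0.40 lay nearer the RelB siRNA mean. A share of 0.93 for all genes would put each nearer to 0. A mixture is thus argued against as the whole cause, on genes picked for their large differences. A mixture as a part of the cause stays open. A weaker knockdown stays open as well, since SMARCA4 on array 1 differed by -0.0691 (log2, SE 0.23) from the mean of arrays 2 and 3, and handling of the RNA of arrays 2 and 3 was not tested.

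CYP1A1 and CYP1B1 were lower on the RelB siRNA arrays than on the BRG1 siRNA arrays. Normalization is argued against as the whole cause, because the log2 differences nearest to 0 under the 4 other ways to correct and scale the signals were -1.93 for CYP1B1 and -1.04 for CYP1A1, called in each, although the log2 ratios of the raw mean signals, with their background, were smaller, -1.497 and -0.86. The departure of BRG1 siRNA arrays 2 and 3 from array 1 is argued against as well: on array 1 the lower of the places of the 2 genes was 1.09, where 1 is the mean of arrays 2 and 3 and 0 that of the RelB siRNA arrays. Lower activity of the aryl hydrocarbon receptor under RelB siRNA may explain the difference: the median over 5 tested receptor targets not seen before was -0.38, with ALDH3A1 at -1.10 (adjusted p = 0.026) and TIPARP at -0.92 (adjusted p = 0.039), against 0.43 for CYP2S1 (adjusted p = 0.2). The targets go both ways, and the receptor's activity was not measured.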

How the results depend on the processing

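The normalization of the 2 compared groups alone, and the normalization of RelB and BRG1 siRNA arrays without BRG1 siRNA replicate 1, were chosen only after the data were seen. A block for slides was not run because slides are not given.

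Counts of genes fell under a filter and a threshold that leave fewer genes, and moved when single arrays were left out. With genes detected on all 12 arrays, 336 genes differed between Edar-HaCaT and HaCaT, 4726 under RelB siRNA, 5052 under BRG1 siRNA and 148 between the siRNAs; 144 and 137 genes of the lines went the opposite way under RelB and BRG1 siRNA and 4159 the same way under both, and 9 lists shifted under RelB siRNA and 9 under BRG1 siRNA. At an adjusted p under 0.01 the counts were 233 between the lines and 38 between the siRNAs, with 111 and 105 genes that went the opposite way. The cause of the remaining changes was not tested. Array weights gave 1614 genes between the lines, 2202 between the siRNAs, and 770 and 717 that went the opposite way. Between the siRNAs the count was 438 with normexp without detection p-values, 422 with the deposited scores, 11 when only the compared groups were fitted, 11 when those were also normalized alone and 1626 without BRG1 replicate 1 on its own normalization.

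The replicate number as a block, tried although the labels do not say that the numbers pair the samples, gave 420, 7340, 7724 and 91 genes in the 4 comparisons, of which the last alone differs more than 1.5 times from its count of 267. Arrays of the same number correlated by -0.36 to 0.21 in their deviations from the group mean, so that the numbers do not pair the arrays.

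Without 1 array at a time, genes ranged from 270 to 883 between the lines, 6890 to 7906 under RelB siRNA, 7367 to 8092 under BRG1 siRNA and 29 to 2174 between the siRNAs, 127 to 400 and 123 to 403 went the opposite way, and 6232 to 6837 the same way. The log2 change of RELB under RelB siRNA ranged from -1.78 to -1.56 and that of SMARCA4 under BRG1 siRNA from -0.56 to -0.46. Between the siRNAs RELB ranged from -0.23 to 0.15 and SMARCA4 from -0.23 to -0.17. Lists ranged from 7 to 9, 17 to 19, 18 to 19 and 9 to 12 in the 4 comparisons.

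With an estimated correlation camera called 1, 2, 2 and 0 lists. Fry, which does not compare a list with other genes, called 24, 34, 34 and 27 in either direction, and 30 and 32 in one direction under RelB and BRG1 siRNA. By fry the placode list went down while its median was 0.32 under RelB siRNA and 0.28 under BRG1 siRNA, and so did the inflammatory list with a median of 0.46 under BRG1 siRNA.

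Another probe of the same gene had the other sign for POLA1 between the lines (0.22), BID (0.60), KRT18 (1.22), MUC1 (0.029), RPL14 (-0.57) and SS18L1 (-0.076) under RelB siRNA, and BID (0.088), DKK3 (-0.020), KRT18 (1.502), MUC1 (0.17), RPL14 (-1.53) and YWHAZ (-0.031) under BRG1 siRNA. Of these, BID under RelB siRNA, KRT18 under both and RPL14 under BRG1 siRNA were called in the other direction. The mean of a gene's probes gave the other sign for KRT18 (0.17 under RelB siRNA, 0.33 under BRG1 siRNA) and RPL14 (-0.22 under BRG1 siRNA). The cause was not tested.

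Of all settings of named genes, 174 of 2509 lost a call between the lines, 27 of 3718 under RelB siRNA, 51 of 3746 under BRG1 siRNA and 246 of 1843 between the siRNAs, while 21, 0, 1 and 70 gained one and the others kept direction and call apart from the changes of sign above. Median centring moved the median of all genes by -0.18 under RelB siRNA and -0.11 under BRG1 siRNA. The share of higher genes among the called went from 62.0% to 73.5% between the lines with the deposited scores, and between the siRNAs from 62.2% to 42.6% without background correction, 73.1% with median centring, 79.9% with cyclic loess and 36.4% with the groups normalized alone. For RelB siRNA against scrambled it went from 47.3% to 40.4% with median centring and 52.2% with cyclic loess. For BRG1 siRNA against scrambled it went from 47.7% to 41.15% and 51.3%. Which direction held more genes thus turned with cyclic loess in both. Signal over background limits genes such as EDAR, above background on 0 of 12 arrays, and the size of changes whose lower group is at background.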

Other observations

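The tests of the origin of the RNA on the scrambled arrays, of an effect of the siRNAs and of normalization were chosen only after the result was seen.

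Of the aryl hydrocarbon receptor targets, TIPARP, which encodes a feedback inhibitor of the receptor, was higher in Edar-HaCaT than in HaCaT by 1.44 (log2, adjusted p = 0.001), like CYP1A1, while the median over 5 tested targets was 0.18 and ALDH3A1, at 0.18, was not called (adjusted p = 0.77). Of other leukocyte markers, 3 of 9 B lineage markers and 1 of 9 myeloid markers were above background on all 6 scrambled arrays, and 0 and 2 on all 6 siRNA arrays. Monocyte marker CD14 was higher on the RelB and BRG1 siRNA arrays than on the scrambled arrays, at least 5.06-fold and 8.12-fold. Of fibroblast markers THY1 was at least 25.5-fold and 24.7-fold lower on the siRNA arrays; THY1 is also a T cell gene in some species. Of 12 tested housekeeping genes 0 were called higher and 7 lower under RelB siRNA against scrambled siRNA, and 3 higher and 5 lower under BRG1 siRNA, and the list was not called by camera (adjusted p = 0.088 and 0.52), while fry called it down (adjusted p = 4.4e-04 and 0.016). Of its members PPIA had -2.28 and -1.75.

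Of 14 basal keratinocyte markers, 9 were above background on 0 of the 6 scrambled arrays, of HaCaT and of Edar-HaCaT, which the labels give as keratinocytes. That the cells expressed these genes without the RelB and BRG1 siRNAs is argued against by the HaCaT scrambled arrays, which received neither siRNA. On these, 3 of 14 basal markers were above background on all 3. That count is part of the pattern itself and no separate test. A rise under the siRNAs in cells that lacked these transcripts was not tested. From the scrambled arrays 6737 genes differed the same way under both siRNAs and 0 the opposite way. An effect particular to either siRNA is thus argued against as the whole cause. The HaCaT scrambled arrays, which received neither siRNA, had 13 of 15 T lineage and 10 of 10 pan-leukocyte markers above background on all 3. An effect common to both siRNAs cannot have put these transcripts there, and is argued against as the whole cause. A part of such an effect in the difference between the 2 sets of arrays stays open. Normalization is argued against by the raw signals, whose median log2 ratio over the basal markers, siRNA over scrambled arrays, was 3.94. RNA of a leukocyte or T-lineage cell on the scrambled arrays is a candidate explanation: 13 of 15 T lineage markers were above background on all 6 scrambled arrays and 0 on all 6 siRNA arrays, with CD247 at 12.98, CD3D at 12.86, CD6 at 11.39 and LAT at 11.17 on the Edar-HaCaT scrambled arrays. CD3E of this list and PTPRC of the pan-leukocyte list are also in the immune cell list, no sort or gate is named in the labels, and how such RNA would have come onto the arrays was not tested.

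Chance as a source of each count was examined by other splits of the arrays. With 10 splits of 6 arrays a share under 0.05 cannot be reached in a single comparison. Between Edar-HaCaT and HaCaT the real split gave 579 genes and the highest other 0 (1 split with as many), for RelB siRNA against scrambled 7485 and 0 (1 split), and for BRG1 siRNA against scrambled 7872 and 0 (1 split). A split that mixes the groups puts their difference into the spread. Where groups differ much, 0 calls in such splits are nearly set in advance, so the contrast is no support. The lists called, adjusted within each comparison, were 9 against a highest other of 3, 19 against 16 and 19 against 18, with 1 split each. For the genes that went the opposite way under RelB siRNA, 3 of 100 drawn splits of 9 arrays gave as many as the real 270, for those under BRG1 siRNA 3 gave as many as 264, and for genes that went the same way under both 2 gave as many as 6737. The highest others were 6547, 6971 and 6765. The structure of the samples, in 2 sets of arrays, sets these counts, so the splits say nothing on chance for shared genes.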
